A study of Homo sapiens with 39 samples.

How the data were processed

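RNA was measured in 39 formalin-fixed, paraffin-embedded endometrial tumours, 1 library per patient, by sequencing after exome capture. The labels place all 39 in 1 group. The deposited file holds raw counts per Ensembl gene, whole numbers for 19619 genes, and per the submitters' processing notes FastQC 0.12.1, cutadapt 3.4, Trim Galore 0.6.7, STAR 2.7.9a, Salmon 1.10.1, SAMtools 1.17, MultiQC 1.19 and the GRCh38.p14 genome were used. The role of each tool, the annotation release and whether strand was counted are not given in the sources used here. The authors filtered the genes before depositing the counts, per the file's name, by a rule that is not given, and every gene in the file has at least 1 count in at least 32 tumours. All 39 columns were used.

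Counts were scaled with edgeR 4.0.16 by the trimmed mean of M-values (TMM), and log2 counts-per-million (CPM) were computed with a prior count of 2. Gene symbols were matched for 19276 of the 19619 genes. XIST, TSIX and Y-linked genes, 15 genes in all, were left out, since they mark a person's sex. The function filterByExpr, with a minimum count of 10 and a minimum total of 15, kept 15770 genes and removed 3834. For each of RB1, CDKN2A, CCNE1 and ESR1, its own log2 CPM was scaled to mean 0 and SD 1 over the tumours and fitted as a continuous covariate with edgeR's robust quasi-likelihood test, with that gene left out of the 15769 genes tested. Slopes are therefore log2 units per SD of the regulator, where 1 SD was 0.56, 1.51, 1.91 and 1.26 log2 units for RB1, CDKN2A, CCNE1 and ESR1. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. They measure the spread between tumours of 39 different patients.

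Genes were named by a rule. For each regulator these were the 8 genes with the largest positive and the 8 with the largest negative slope among those past the threshold, with a mean of at least 3 log2 CPM and a Spearman rho with the regulator of at least 0.4 in size. Of these, 1 gene for ESR1 is not reported here. To these were added up to 4 called members of each list that passed, up to 5 called G1/S regulators and up to 5 called members of the regulator's own locus list. The regulators, lists, pairs, tests and naming rule were fixed before the data were examined.

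There were 24 gene lists. They held G1/S regulators, E2F targets, G2/M and mitosis genes, oestrogen-responsive genes, p53 targets, Wnt/beta-catenin targets, interferon response genes, hypoxia and glycolysis genes, ribosomal protein genes and immediate early genes. Further lists were the neighbours of RB1 (13q14), CDKN2A (9p21), CCNE1 (19q12) and ESR1 (6q25), where the lists for CDKN2A and CCNE1 also hold genes beyond the named band. Marker lists covered T and NK cells, B and plasma cells, macrophages and monocytes, fibroblasts, smooth muscle, endothelium, adipocytes, epithelium, ciliated epithelium and red blood cells. A list's score in a tumour was the mean over its measured members of log2 CPM scaled to mean 0 and SD 1, without the regulator it was compared with. Scores were correlated with the 4 regulators by Pearson's r and Spearman's rho, with two-sided permutation tests of 100000 resamples and Benjamini-Hochberg adjustment over the 96 relations, and a list was called on its Pearson p. The same test was used for 10 pairs of measures fixed in advance and for 22 relations with library size and genes detected. Each r was computed again without the 2 tumours farthest from the median of the measure on the x axis. A gap of 0.75 SD between neighbouring tumours with at least 6 tumours on each side was set as the rule for separate clusters. Limma 3.58.1's camera tested the lists with a correlation between genes estimated for each list, and with the preset correlation of 0.01.

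Gene positions came from the RefSeq annotation of GRCh38.p14 by symbol, for 14927 of the tested genes, and the GC share of transcripts came from GENCODE release 29, for 97.8% of the genes. The SD of each G1/S regulator was ranked among the 500 genes nearest in mean, where genes removed by the count filter were included.

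Total counts per tumour ran from 4698861 to 62740534, a ratio of 13.4, and the 100 most abundant genes held 13% to 19.5% of them. The highest correlation of a tumour with another was 0.943 on log2 CPM. No reads were available, so PCR copies could not be removed and error from counting alone is a lower limit. The fits were tested on simulated counts drawn from the real means, spreads and library sizes, with 200 of 15769 genes changed. At true slopes of 0.25, 0.5 and 1 the share recovered was 5.88%, 39.4% and 87.9% with the RB1 covariate, 2.94%, 39.4% and 86.4% with that of CDKN2A, 5.88%, 39.4% and 80.3% with that of CCNE1, and 11.8%, 51.5% and 93.9% with that of ESR1. False calls were 4.35%, 3.41%, 2.35% and 3.7% of calls. Each gene was drawn independently there, with no variation shared between genes beyond library size. These shares therefore do not carry over to the real counts, where genes vary together. With the real counts and shuffled covariates, 9, 11, 8 and 14 of 25 orderings gave at least 1 call. In 60 simulated pairs of measures at each true r over 39 tumours, the permutation test gave p under 0.05 in 1.67% at r = 0, 91.7% at r = 0.5 and 100% at r = 0.8.

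Alternatives planned for the gene counts were DESeq2's size factors, the Wald test of DESeq2 1.42.0, limma voom with quality weights, no filter on low counts, normal scores of the regulator, leaving out the 2 farthest tumours, library size and genes detected as covariates, and fibroblast and T cell scores as covariates. For lists and pairs they were camera, DESeq2's size factors, partial correlations, the 2 farthest tumours, Spearman's rho and a prior count of 0.5. Added after seeing the data were each tumour's slope of log2 CPM on GC share as a covariate, the macrophage score as a covariate, leaving out the 5 tumours under 10000000 counts, DESeq2 and limma for ESR1 without the 2 farthest tumours, relations between the lists, relations of genes with neighbours on their chromosome, and a list of NRF2 targets. For each regulator, its values were also shuffled over the tumours 25 times and the fit repeated. Computations used R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.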

Results

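RNA from formalin-fixed, paraffin-embedded tumour tissue of 39 patients with endometrial cancer was sequenced after exome capture, in which probes pull down coding transcripts from degraded RNA. The 39 tumours formed a single group with 1 library per patient. The title of the series asks whether RNA signatures of RB function relate to the response to CDK4/6 inhibitors. The labels give no response, treatment or batch, so genes were compared across tumours along the levels of RB1, CDKN2A, CCNE1 and ESR1. Total counts per tumour ran from 4698861 to 62740534 (median 30965064), 5 tumours had fewer than 10000000, and 15700 to 19317 genes (median 17529) had at least 10 counts. The first principal component held 16.5% of the variance of log2 counts-per-million (CPM) and followed log2 library size (Pearson r = 0.832, permutation p = 1e-05, adjusted p = 0.00022 over 22 relations). Spearman's rho was 0.771 (p = 1e-05, adjusted p = 0.00022). These p-values are the smallest that 100000 permutations can give, and r was 0.77 without the 2 tumours farthest from the median library size.

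RB1 (ENSG00000139687, chromosome 13, 48303751 to 48481890 on GRCh38.p14), whose protein restrains the E2F transcription factors, had a mean of 7.95 ± 0.56 log2 CPM (SD, n = 39) and a 7.93-fold range, from 515 to 20016 counts. Its relative RBL2 stood at 8.08 ± 0.40 log2 CPM. CDKN2A (ENSG00000147889, chromosome 9, 21967752 to 21995324), which encodes the CDK4/6 inhibitor p16 and also ARF, had far fewer counts. Its mean was 1.94 ± 1.51 log2 CPM, with a 115-fold range and 1 tumour under 10 counts. CPM are not scaled for transcript length or capture, so levels of different genes cannot be read as RNA amounts. CCNE1 (ENSG00000105173, chromosome 19, 29811991 to 29824312), the cyclin E1 gene, varied 80-fold around 3.38 ± 1.91 log2 CPM, and its SD exceeded that of 94.4% of the 500 genes nearest to it in mean level. CCND1, which encodes cyclin D1, varied 27.3-fold (5.36 ± 1.2 log2 CPM, percentile 91.8), and MYC lay at percentile 84.2 (4.71 ± 1.01 log2 CPM). The kinase genes differed less, with CDK4 at 4.95 ± 0.56, CDK6 at 3.26 ± 0.84 and CDK2 at 3.85 ± 0.48 log2 CPM, and CDK2, E2F4 and FBXW7 had SD percentiles of 5.8, 1.8 and 12. CDKN2D had too few counts to compare, with fewer than 10 in 20 tumours.

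**Figure D1:**
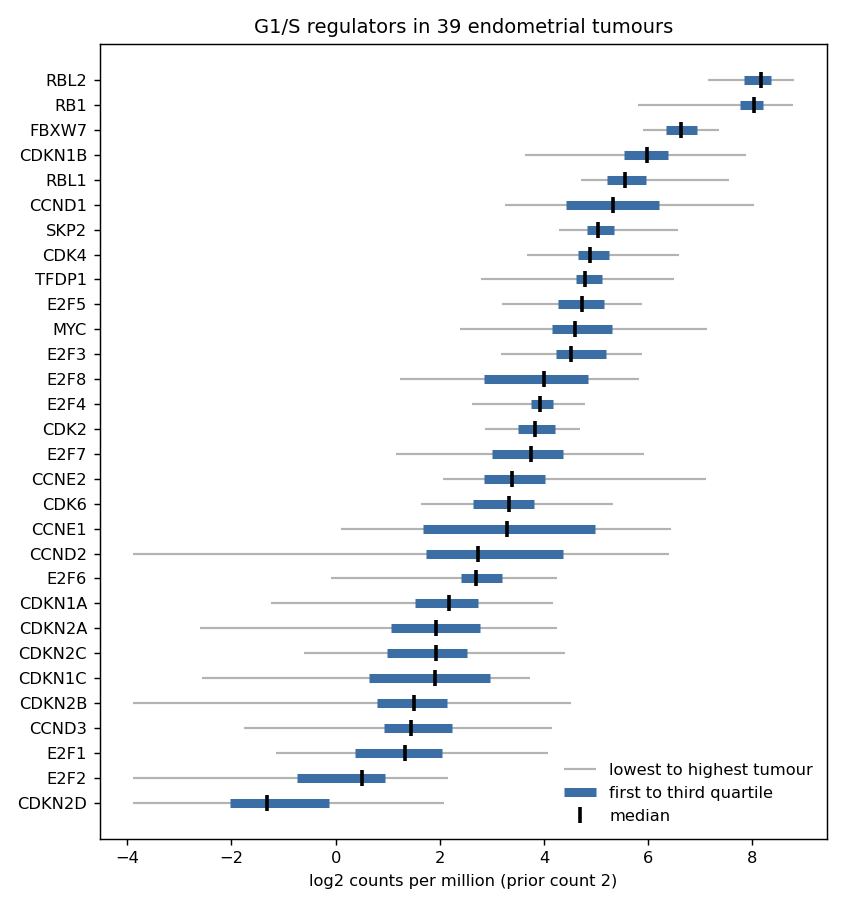
Levels of 30 G1/S regulators in 39 endometrial tumours, as log2 CPM with a prior count of 2, with the lowest and highest tumour (grey line), the quartiles (blue bar) and the median (black tick). CCNE1 spans an 80-fold range, against 7.93-fold for RB1.

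Of 10 relations between pathway measures fixed in advance, 4 passed. The score of E2F targets, genes of DNA replication driven by E2F factors, was higher in tumours with more CCNE1 (Pearson r = 0.555, permutation p = 0.00041, adjusted p = 0.00205 over 10 pairs). Spearman's rho was 0.551 (p = 0.00046, adjusted p = 0.0023), with r = 0.63 without the 2 farthest tumours and adjusted p = 0.116 by limma's camera with an estimated correlation between genes. The score was lower in tumours with more ESR1, the oestrogen receptor gene (r = -0.429, p = 0.00365, adjusted p = 0.0122, and 0.278 by camera with an estimated correlation). Spearman's rho was -0.442 (p = 0.00523, adjusted p = 0.0131). Without the 2 tumours farthest from the median of ESR1 r was -0.325 (adjusted p = 0.1), so the call rests on those 2 while most of the size of r remained. The score of oestrogen-responsive genes was higher with ESR1 (r = 0.422, p = 0.00592, adjusted p = 0.0148). Spearman's rho was 0.472 (p = 0.00274, adjusted p = 0.00913), with r = 0.434 without the 2 farthest tumours and adjusted p = 0.329 with an estimated correlation. The E2F target and G2/M scores rose together (r = 0.951, rho = 0.942, both p = 1e-05 and adjusted p = 0.0001, r = 0.942 without the 2).

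The other 6 pairs did not pass the permutation test. RB1 gave r = -0.114 with the E2F target score (p = 0.5, adjusted p = 0.556), rho = 0.0581 (p = 0.724, adjusted p = 0.905) and r = 0.174 without the 2 farthest tumours. CDKN2A gave r = 0.141 with that score (p = 0.396, adjusted p = 0.556), rho = 0.219 (p = 0.179, adjusted p = 0.357) and r = 0.326 without the 2. CCND1 gave r = 0.0499 with it (p = 0.762, adjusted p = 0.762), rho = 0.034 (p = 0.838, adjusted p = 0.905) and r = -0.0768 without the 2. RB1 with CDKN2A gave r = -0.158 (p = 0.332, adjusted p = 0.556), rho = -0.0202 (p = 0.905, adjusted p = 0.905) and r = 0.167 without the 2. CDKN2A with CCND1 gave r = -0.119 (p = 0.47, adjusted p = 0.556), rho = -0.164 (p = 0.319, adjusted p = 0.531) and r = -0.17 without the 2. ESR1 with CCND1 gave r = 0.152 (p = 0.365, adjusted p = 0.556), rho = 0.0779 (p = 0.639, adjusted p = 0.905) and r = -0.0571 without the 2. No measure split the tumours into clusters of at least 6, the widest gap with 6 or more on each side being 0.505 SD. Wider gaps set single tumours apart, with 1 tumour 2.73 SD below the next for ESR1 and 1.58 SD for CDKN2A, and 2 tumours 1.94 SD below the next for RB1.

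Among the genes with the steepest increase along RB1, LTF (lactoferrin) was higher by 1.5 ± 0.39 log2 units per SD of RB1 (slope ± SE, n = 39, as for all slopes), HP (haptoglobin) by 1.42 ± 0.36, and SERPINA1 (alpha-1 antitrypsin) by 1.05 ± 0.32. CLU (clusterin) was higher by 0.97 ± 0.22 and C3 (complement) by 0.76 ± 0.20, and these 5 genes had adjusted p from 0.00699 to 0.0327 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. IDH1 (0.67 ± 0.14) and LACC1 (0.68 ± 0.16) were higher too. The steepest decreases were in MUC12, a mucin gene (-1.67 ± 0.50), CCDC136 (-1.19 ± 0.22), RYR1, a calcium channel gene (-1.09 ± 0.26), and RASA4 (-1.0 ± 0.22). APOBR (-0.99 ± 0.26), LMTK3 (-0.96 ± 0.21), CHMP1A (-0.92 ± 0.18) and ZSWIM9 (-0.91 ± 0.27) followed, and these 8 had adjusted p from 0.0031 to 0.0343 by the same test. Of all 22 genes named for RB1, 2 stayed called with library size and genes detected in the model. With each tumour's GC trend 3 did, and without the 5 tumours under 10000000 counts 4 did. RASA4 shares sequence with the near-identical RASA4B, and HP with HPR, so the split of reads between the copies is uncertain. Among G1/S regulators, 0 of 28 were higher and 2 lower over all genes, and 2 higher (RBL2 and CCND1) and 3 lower adjusted over the list alone (edgeR, 4026 of all genes at an unadjusted p under 0.05). CCNE2 (-0.52 ± 0.16, adjusted p = 0.0382) and E2F1 (-0.51 ± 0.16, adjusted p = 0.0433, edgeR, Benjamini-Hochberg), both activators of S phase entry, were the 2 over all genes, and CCND3 (-0.43 ± 0.15) joined them in the list alone. RBL2, CCND1 and CCND3 were named after their values were seen.

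By Pearson's r over all tumours, genes beside RB1 in 13q14 were the 1 of 24 lists whose score passed with RB1 (r = 0.821, permutation p = 1e-05, adjusted p = 0.00096 over 96 list relations). Spearman correlation was 0.707 (p = 1e-05, adjusted p = 0.00096), with r = 0.647 without the 2 farthest tumours. With an estimated correlation between genes the list kept its call (adjusted p = 0.00479). By rank, epithelial markers and B and plasma cell markers passed with RB1 as well, and by Pearson's r 3 lists passed given library size and genes detected and 4 without the 2 farthest tumours. For epithelial and for B and plasma cell markers, partial r given library size and genes detected was small (0.108 and -0.155). ITM2B (ENSG00000136156, chromosome 13, 48233206 to 48270357), next to RB1, was higher by 0.54 ± 0.09 (adjusted p = 0.00167), and FNDC3A by 0.39 ± 0.10. SUCLA2 was higher by 0.30 ± 0.09, KPNA3 by 0.29 ± 0.06 and LCP1, the gene of the leucocyte protein L-plastin, by 0.66 ± 0.19 (edgeR, Benjamini-Hochberg, adjusted p from 0.00442 to 0.0285 for the last 4). These 5 of 18 members passed over all genes and 9 of 18 adjusted over the list alone. LPAR6 lies within an RB1 intron, so reads of the 2 genes cannot be told apart there if strand was not counted. RB1 itself was higher in tumours with larger libraries by rank (Spearman rho = 0.574, p = 0.00023, adjusted p = 0.00253 over 22 relations), while Pearson r was 0.445 (p = 0.00508, adjusted p = 0.0559) and 0.266 without the 2 tumours farthest in library size. In all, 1300 of 15769 genes were associated with RB1, 455 higher and 845 lower (edgeR's quasi-likelihood test, adjusted p under 0.05). That count was 26 with library size and genes detected in the model, 53 with each tumour's GC trend and 103 without the 5 tumours under 10000000 counts. ITM2B and CCDC136 were the 2 of 22 named genes called under each of these 3. Limma with quality weights, which also weight the tumours, called 1273 genes for RB1, 850 higher and 423 lower. Without the 5 tumours under 10000000 counts edgeR called 52 higher and 51 lower. The balance of directions thus differed between settings, with the test and with the tumours used.

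In tumours with more CDKN2A, IGF2BP2, an RNA-binding protein gene, was higher by 1.09 ± 0.26 log2 units per SD, the interferon-induced MX2 by 0.82 ± 0.16, COL9A2 by 0.75 ± 0.17 and EPPK1 by 0.74 ± 0.13. FGFRL1 was higher by 0.68 ± 0.17, AKR1B1 by 0.58 ± 0.13, ABCA3 by 0.57 ± 0.14 and HELZ2 by 0.56 ± 0.11, and these 8 had adjusted p from 0.00233 to 0.0486 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Lower were TFPI2, a protease inhibitor gene (-0.95 ± 0.21), GUCY1A1, a subunit of the nitric oxide receptor (-0.66 ± 0.11), PDK4 (-0.65 ± 0.16) and complement C5 (-0.63 ± 0.11). Also lower were PALLD (-0.55 ± 0.14), PTGR1 (-0.45 ± 0.09), CHP1 (-0.41 ± 0.09) and FDFT1, which encodes squalene synthase (-0.40 ± 0.10), and these 8 had adjusted p from 0.00112 to 0.048 by the same test. The CDKN2A measure cannot part p16 from ARF. Of 15769 genes 102 passed, 55 higher and 47 lower. Without the 2 tumours farthest from the median of CDKN2A the count was 435, 356 higher and 79 lower, and limma over all tumours called 49. Of the 102 genes, 58 and 15 stayed called in the same direction in these 2 settings.

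The oestrogen-responsive score was lower in tumours with more CDKN2A (Pearson r = -0.532, permutation p = 0.00044, adjusted p = 0.00845 over 96 relations). Spearman correlation was -0.575 (p = 0.00017, adjusted p = 0.00408), with r = -0.567 without the 2 farthest tumours and adjusted p = 0.116 with an estimated correlation. CA12, a carbonic anhydrase gene, was the 1 of 17 members lower over all genes (-0.75 ± 0.14, adjusted p = 0.00384, edgeR, Benjamini-Hochberg). Adjusted over the list alone, 4 of 17 were lower, the others being PDZK1, IGFBP4 and XBP1, named after their values were seen. CA12 turned to 0.0092 without the 2 farthest tumours (adjusted p = 0.988). The score of genes around CCNE1 on 19q was higher with CDKN2A (r = 0.478, p = 0.00319, adjusted p = 0.0255), with 0 of 10 members past edgeR's test over all genes and 6 adjusted over the list alone, of which 2 lie within 2 Mb of CCNE1. Spearman correlation was 0.419 (p = 0.00817, adjusted p = 0.049), with r = 0.469 without the 2 farthest tumours and adjusted p = 0.116 with an estimated correlation. The p53 target score was lower (r = -0.443, p = 0.0047, adjusted p = 0.0305), with 0 of 19 members past the test and 1, SESN1, adjusted over the list alone. Spearman correlation was -0.318 (p = 0.0491, adjusted p = 0.143), with adjusted p = 0.116 with an estimated correlation. Its call rests on the 2 farthest tumours (adjusted p = 0.169 without them), where r was -0.303. The fibroblast marker score was lower as well (r = -0.408, p = 0.00982, adjusted p = 0.0483), and r was -0.368 without the 5 tumours under 10000000 counts (adjusted p = 0.127). Of its 15 members 0 passed the test over all genes or over the list alone. Spearman correlation was -0.339 (p = 0.0347, adjusted p = 0.104), with r = -0.536 without the 2 farthest tumours and adjusted p = 0.281 with an estimated correlation. For CDKN2A, edgeR gave 2413 genes at an unadjusted p under 0.05, DESeq2 called 458, and 1 of 3 lists held with fibroblast and T cell scores in the model, where the fibroblast list itself was not tested. That list, oestrogen-responsive genes, had r = -0.437 there, just under the threshold (permutation test, adjusted p = 0.0487). The p53 targets (r = -0.406, adjusted p = 0.0588) and the genes around CCNE1 (r = 0.397, adjusted p = 0.0808) lost their calls there at a similar r.

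Tumours with more CCNE1 had more RNA of mitosis and DNA replication genes. Of 29 G2/M genes, 27 were higher, among them KIF2C (1.2 ± 0.15 log2 units per SD) and TPX2 (1.16 ± 0.15), both spindle proteins, MYBL2 (1.16 ± 0.18) and UBE2C (1.16 ± 0.19). These 4 had adjusted p from 9.11e-06 to 0.000251 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. All 29 passed adjusted over the list alone. Of 38 E2F targets, 17 were higher over all genes and 28 adjusted over the list alone. They included the checkpoint kinase gene CHEK1 (0.75 ± 0.14), the replication genes MCM10 (0.73 ± 0.14) and GINS1 (0.68 ± 0.17), and UHRF1 (0.72 ± 0.13). The 5 of 28 G1/S regulators that were higher were E2F1 (0.90 ± 0.17), E2F8 (0.77 ± 0.17), CDKN2A (0.71 ± 0.21), E2F2 (0.71 ± 0.22) and RBL1 (0.33 ± 0.09). RBL2, a relative of RB1 linked to quiescence and named after its value was seen, was lower (-0.23 ± 0.05, adjusted p = 0.00758, edgeR, Benjamini-Hochberg). Adjusted over the list alone, 12 were higher and 1 lower. The G2/M score rose with CCNE1 (Pearson r = 0.634, permutation p = 3e-05, adjusted p = 0.00144 over 96 relations, and 0.116 by camera with an estimated correlation). Its Spearman rho was 0.611 (p = 5e-05, adjusted p = 0.0024), with r = 0.711 without the 2 farthest tumours. The G1/S score rose as well (r = 0.585, p = 0.00016, adjusted p = 0.00512, and 0.116 with an estimated correlation). Its rho was 0.602 (p = 0.00012, adjusted p = 0.00384), with r = 0.605 without the 2. For E2F targets, r = 0.555 and rho = 0.551 had adjusted p = 0.00845 and 0.00631 over the 96, and 0.116 with an estimated correlation.

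**Figure D2:**
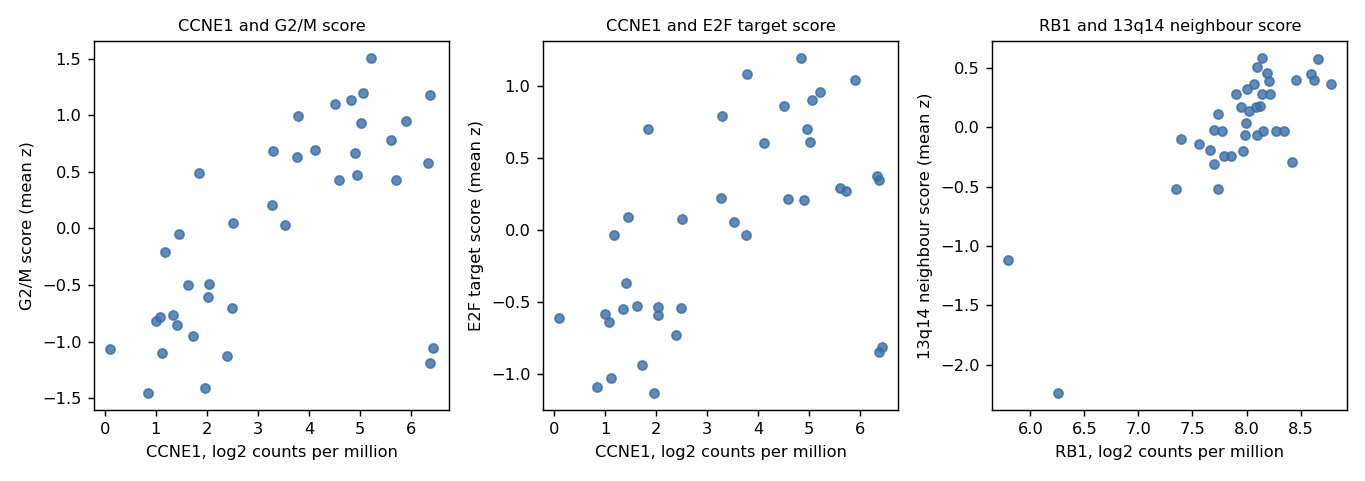
Each point is 1 of 39 tumours, with the regulator in log2 CPM on the x axis and the list score (mean z) on the y axis. The G2/M score (r = 0.634) and the E2F target score (r = 0.555) rise with CCNE1 with scatter, 2 tumours with CCNE1 at 6.37 and 6.43 have low scores, and the 13q14 score rises with RB1 (r = 0.821).

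Interferon-induced genes were higher in tumours with more CCNE1, with 12 of 20 members past the test over all genes and 20 of 20 adjusted over the list alone. IFIT1 was higher by 1.21 ± 0.23, IFI44L by 1.16 ± 0.22, IFI6 by 0.95 ± 0.27 and MX1 by 0.91 ± 0.19. The interferon score gave r = 0.467 (permutation p = 0.00258, adjusted p = 0.0225). Spearman correlation was 0.398 (p = 0.0122, adjusted p = 0.0558), with r = 0.481 without the 2 farthest tumours and adjusted p = 0.23 with an estimated correlation. Targets of Wnt/beta-catenin were lower, 8 of 13 over all genes and 11 of 13 adjusted over the list alone. The Wnt antagonists NKD1 (-1.56 ± 0.30), NOTUM (-1.47 ± 0.40) and APCDD1 (-0.98 ± 0.24) were lower, as was BMP4 (-0.96 ± 0.24). The Wnt score gave r = -0.485 (p = 0.0017, adjusted p = 0.0164). Spearman correlation was -0.377 (p = 0.0186, adjusted p = 0.0778), with r = -0.434 without the 2 farthest tumours and adjusted p = 0.245 with an estimated correlation. Outside the lists, LRP2 (1.36 ± 0.30), GLDC, a glycine cleavage enzyme gene (1.22 ± 0.34), and the aminopeptidase gene ANPEP (1.11 ± 0.28) were higher with CCNE1. AMACR (-1.52 ± 0.25), PROX1 (-1.51 ± 0.28), ADAM23 (-1.40 ± 0.30), C4BPA (-1.36 ± 0.36), ACSL5 (-1.29 ± 0.23), EPHB3 (-1.28 ± 0.21) and MME (-1.27 ± 0.24) were lower. All 10 of these had adjusted p from 0.000251 to 0.0276 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

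Oestrogen-responsive genes were lower in tumours with more CCNE1 as a score (r = -0.53, permutation p = 0.00054, adjusted p = 0.00864). Spearman correlation was -0.547 (p = 0.00031, adjusted p = 0.0056), with r = -0.56 without the 2 farthest tumours and adjusted p = 0.116 with an estimated correlation. Of its 17 members 0 passed edgeR's test over all genes and 2, PGR (-0.85 ± 0.27) and GREB1 (-0.64 ± 0.20), adjusted over the list alone, both named after their values were seen. Genes around CCNE1 on 19q were higher (r = 0.454, p = 0.00171, adjusted p = 0.0164), with 4 of 10 over all genes and 7 adjusted over the list alone. Spearman correlation was 0.478 (p = 0.00238, adjusted p = 0.0254), with r = 0.491 without the 2 farthest tumours and adjusted p = 0.275 with an estimated correlation. They were ANKRD27 (0.52 ± 0.11), PDCD5 (0.49 ± 0.13), URI1 (0.36 ± 0.08), the gene next to CCNE1 at 29923657 to 30016612, and ZNF507 (0.29 ± 0.08), and all but URI1 lie at 32345610 to 32675180, over 2 Mb from CCNE1. The score of genes beside RB1 in 13q14 was lower (r = -0.452, p = 0.00153, adjusted p = 0.0164), with FNDC3A (-0.38 ± 0.08) the 1 of 18 members past the test over all genes and TRIM13 beside it adjusted over the list alone. Of the 18 slopes 5 were positive. Spearman correlation was -0.468 (p = 0.00312, adjusted p = 0.0272), with r = -0.491 without the 2 farthest tumours and adjusted p = 0.279 with an estimated correlation. The fibroblast marker score was lower (r = -0.416, p = 0.00793, adjusted p = 0.0448), with PDGFRB (-0.39 ± 0.11) the 1 of 15 members over all genes and COL3A1 beside it adjusted over the list alone. Without the 5 tumours under 10000000 counts that call was lost at the same size (r = -0.415, adjusted p = 0.0699). Spearman correlation was -0.4 (p = 0.012, adjusted p = 0.0558), with r = -0.449 without the 2 farthest tumours and adjusted p = 0.329 with an estimated correlation. Ribosomal protein genes were lower (r = -0.409, p = 0.0101, adjusted p = 0.0483), with RPL7A (-0.35 ± 0.11) and RPL3 (-0.35 ± 0.10), which share reads with pseudogenes, the 2 of 15 over all genes and 10 adjusted over the list alone. Spearman correlation was -0.424 (p = 0.00787, adjusted p = 0.049), with adjusted p = 0.372 with an estimated correlation. The ribosomal relation lay close to the threshold, and its call was lost at a similar r without the 2 farthest tumours (r = -0.395, adjusted p = 0.0625), given library size and genes detected (adjusted p = 0.0663), given fibroblast and T cell scores (0.064) and without the 5 tumours under 10000000 counts (0.117). In all, 801 of 15769 genes were associated with CCNE1, 507 higher and 294 lower (edgeR's quasi-likelihood test, 3285 at an unadjusted p under 0.05). The count was 267 with fibroblast and T cell scores in the model, and 1537 without the 5 tumours under 10000000 counts, where r with the G2/M score was 0.862. With fibroblast and T cell scores 6 of the 9 lists tested held, and besides ribosomal proteins the 13q14 genes (r = -0.257, adjusted p = 0.28) and those around CCNE1 (r = 0.369, adjusted p = 0.0813) did not. Of the lists that held, G2/M genes had r = 0.548 (permutation test, adjusted p = 0.0172). The others had adjusted p = 0.0487, just under the threshold, with r = 0.454 for E2F targets.

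ESR1 (ENSG00000091831, chromosome 6, 151656672 to 152129619) encodes oestrogen receptor alpha and had a mean of 7.56 ± 1.26 log2 CPM. PGR, the progesterone receptor gene that oestrogen induces, was higher by 1.21 ± 0.30 log2 units per SD of ESR1, the secretoglobin gene SCGB2A1 by 1.2 ± 0.29, and HHIP, an inhibitor of hedgehog signalling, by 1.11 ± 0.28. CAPS was higher by 0.96 ± 0.21, ERICH3 by 0.88 ± 0.23, EYA2 by 0.86 ± 0.18, BMPR1B by 0.81 ± 0.20 and CACNA1C by 0.77 ± 0.18, and these 8 had adjusted p from 0.00691 to 0.0341 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. CCDC170, 0.336 Mb from ESR1 on chromosome 6 between gene midpoints, was higher by 0.56 ± 0.15 (adjusted p = 0.0405, edgeR, Benjamini-Hochberg). Steep decreases were in ME1, a source of NADPH (-1.27 ± 0.22), SPP1, the osteopontin gene (-1.13 ± 0.19), and FTL, the ferritin light chain gene with many pseudogenes (-0.85 ± 0.10). VEPH1 (-0.82 ± 0.16), CBR1 (-0.72 ± 0.15), NAMPT (-0.72 ± 0.15) and ALOX5 (-0.67 ± 0.18) were lower too, and these 7 had adjusted p from 4.67e-06 to 0.0409 by the same test. In all, 227 of 15769 genes passed, 65 higher and 162 lower. Without the 2 tumours farthest from the median of ESR1, edgeR called 0 genes (1495 at an unadjusted p under 0.05), DESeq2 68 and limma 50. Of the 227 genes, 16 stayed called in the same direction with DESeq2 and 11 with limma. The 227 genes had a median slope of 0.51 (SE 0.12) in their own direction by edgeR, which was 0.37 (SE 0.19) without the 2.

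Macrophage markers were lower in tumours with more ESR1, 5 of 14 over all genes and 11 adjusted over the list alone. CD68 (-0.67 ± 0.10), C1QB (-0.50 ± 0.12), TYROBP (-0.49 ± 0.11), CD163 (-0.47 ± 0.11) and LAPTM5 (-0.46 ± 0.11), the last named after its value was seen, had adjusted p from 4.82e-05 to 0.0188 (edgeR, Benjamini-Hochberg). The macrophage score gave r = -0.43 (permutation p = 0.00868, adjusted p = 0.0463). Spearman correlation was -0.191 (p = 0.244, adjusted p = 0.434), with adjusted p = 0.116 with an estimated correlation. The G2/M score was lower with ESR1 (r = -0.453, p = 0.00156, adjusted p = 0.0164). Its rho was -0.484 (p = 0.00195, adjusted p = 0.0234), with adjusted p = 0.245 with an estimated correlation. The E2F target score was lower too, where r = -0.429 and rho = -0.442 had adjusted p = 0.027 and 0.0418 over 96 relations, with adjusted p = 0.278 with an estimated correlation. The G1/S score was lower as well (r = -0.427, p = 0.00476, adjusted p = 0.0305). Its rho was -0.376 (p = 0.0186, adjusted p = 0.0778), with adjusted p = 0.245 with an estimated correlation.

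The mitotic kinase gene AURKB (-0.52 ± 0.13) was the 1 of 29 G2/M genes lower over all genes, with 23 lower adjusted over the list alone. GINS1 (-0.57 ± 0.13), ORC1 (-0.45 ± 0.12), FEN1 (-0.38 ± 0.10), MCM5 (-0.33 ± 0.08) and MCM7 (-0.24 ± 0.07), the last named after its value was seen, were the 5 of 38 E2F targets, with 11 lower adjusted over the list alone. CDK4, the target of CDK4/6 inhibitors, was the 1 of 29 G1/S regulators lower over all genes (-0.29 ± 0.07, adjusted p = 0.0156, edgeR, Benjamini-Hochberg), with 4 lower and RBL2 higher adjusted over the list alone. The oestrogen-responsive score was higher, where r = 0.422 and rho = 0.472 had adjusted p = 0.0355 and 0.0263 over 96 relations, with adjusted p = 0.329 with an estimated correlation. PGR was the 1 of 17 higher over all genes, and PGR was higher and CA12 lower adjusted over the list alone. Without the 2 farthest tumours r was -0.147 for macrophages (adjusted p = 0.595), a relation that rests on those 2. There r was -0.38 for G2/M (adjusted p = 0.0742) and -0.303 for G1/S (adjusted p = 0.169), so these calls rest on the 2, as that of E2F targets does, while most of the size of r remained. Given fibroblast and T cell scores, 4 of the 5 lists held and E2F targets did not (r = -0.414, adjusted p = 0.0566). Of those that held, macrophages had adjusted p = 0.0367 (permutation test) and the others 0.0487, just under the threshold. Without the 5 tumours under 10000000 counts r stayed about as large, at -0.423 for G2/M, -0.396 for E2F targets, -0.405 for G1/S, 0.44 for oestrogen-responsive genes and -0.431 for macrophages, though 0 of the 5 lists passed (permutation test, adjusted p from 0.0517 to 0.0699, 6 lists at an unadjusted p under 0.05, and 12 by limma's camera with a preset correlation over all tumours).

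Genes called for both CCNE1 and ESR1 numbered 35, against 11.5 if the lists were independent, and 0 of the 35 had the same direction. CDKN2A and CCNE1 shared 27 called genes, 23 in the same direction, against 5.18, and CDKN2A and ESR1 shared 23, 19 in the same direction, against 1.47. Of the tumours, 1 was among the 2 farthest from the median for both CDKN2A and ESR1. RB1 shared 87 called genes with CCNE1, 0 in the same direction, against 66, 10 with CDKN2A, 0 in the same direction, against 8.4, and 4 with ESR1, 4 in the same direction, against 18.7. These overlaps were counted across genes, which are not independent replicates, and were not tested.

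For 12 lists no relation with the 4 regulators passed by Pearson's r over all tumours, and for each the one with the smallest p is given. Given library size and genes detected, some of them did pass after adjustment (permutation test). With CCNE1 these were hypoxia and glycolysis (partial r = 0.525, p = 0.00054) and smooth muscle (-0.405, p = 0.0105). With RB1 they were adipocytes (0.465, p = 0.00482) and endothelium (0.402, p = 0.0105). Without these covariates, r for these 2 lists was -0.317 and -0.213 without the 2 farthest tumours, and rho was -0.0763 and 0.0502. Both relations with RB1 thus depend on the setting, and the adipocyte score rests on 4 measured members. Smooth muscle markers gave r = 0.365 with ESR1 (permutation p = 0.0189, adjusted p = 0.0741), rho = 0.439 (p = 0.00577, adjusted p = 0.0426) and r = 0.404 without the 2 farthest tumours. Ciliated epithelium gave r = 0.318 with ESR1 (p = 0.0497, adjusted p = 0.17), rho = 0.349 (p = 0.0301, adjusted p = 0.0933) and r = 0.233 without the 2. Genes beside ESR1 in 6q25 gave r = 0.204 with it (p = 0.208, adjusted p = 0.424), rho = 0.299 (p = 0.0652, adjusted p = 0.179) and r = 0.314 without the 2. Immediate early genes gave r = -0.183 with ESR1 (p = 0.26, adjusted p = 0.492), rho = -0.183 (p = 0.263, adjusted p = 0.459) and r = -0.134 without the 2. T and NK cell markers gave r = 0.133 with ESR1 (p = 0.432, adjusted p = 0.61), rho = 0.156 (p = 0.343, adjusted p = 0.568) and r = 0.137 without the 2. Hypoxia and glycolysis genes gave r = 0.313 with CCNE1 (p = 0.0533, adjusted p = 0.171), rho = 0.291 (p = 0.0724, adjusted p = 0.188) and r = 0.347 without the 2.

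Epithelial markers gave r = 0.299 with RB1 (permutation p = 0.0648, adjusted p = 0.183), rho = 0.548 (p = 0.00035, adjusted p = 0.0056) and r = 0.66 without the 2. B and plasma cell markers gave r = -0.341 with RB1 (p = 0.0327, adjusted p = 0.116), rho = -0.43 (p = 0.00647, adjusted p = 0.0444) and r = -0.561 without the 2. By rank, the relations of smooth muscle with ESR1 and of epithelium and of B and plasma cells with RB1 thus passed. Given library size and genes detected, partial r with RB1 was smaller, at 0.108 for epithelium (permutation p = 0.506) and -0.155 for B and plasma cells (p = 0.334). For smooth muscle with ESR1 it was 0.343 (p = 0.0325). The B and plasma cell score rests on 3 measured members. Endothelial markers gave r = 0.294 with RB1 (p = 0.0678, adjusted p = 0.186), rho = 0.0502 (p = 0.763, adjusted p = 0.882) and r = -0.213 without the 2. Adipocyte markers gave r = 0.191 with RB1 (p = 0.25, adjusted p = 0.49), rho = -0.0763 (p = 0.643, adjusted p = 0.792) and r = -0.317 without the 2. Genes around CDKN2A on 9p gave r = -0.36 with CCNE1 (p = 0.0155, adjusted p = 0.0649), rho = -0.409 (p = 0.00937, adjusted p = 0.0506) and r = -0.334 without the 2. Red blood cell genes gave r = 0.307 with CCNE1 (p = 0.0571, adjusted p = 0.177), rho = 0.354 (p = 0.0271, adjusted p = 0.0929) and r = 0.253 without the 2.

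**Figure D3:**
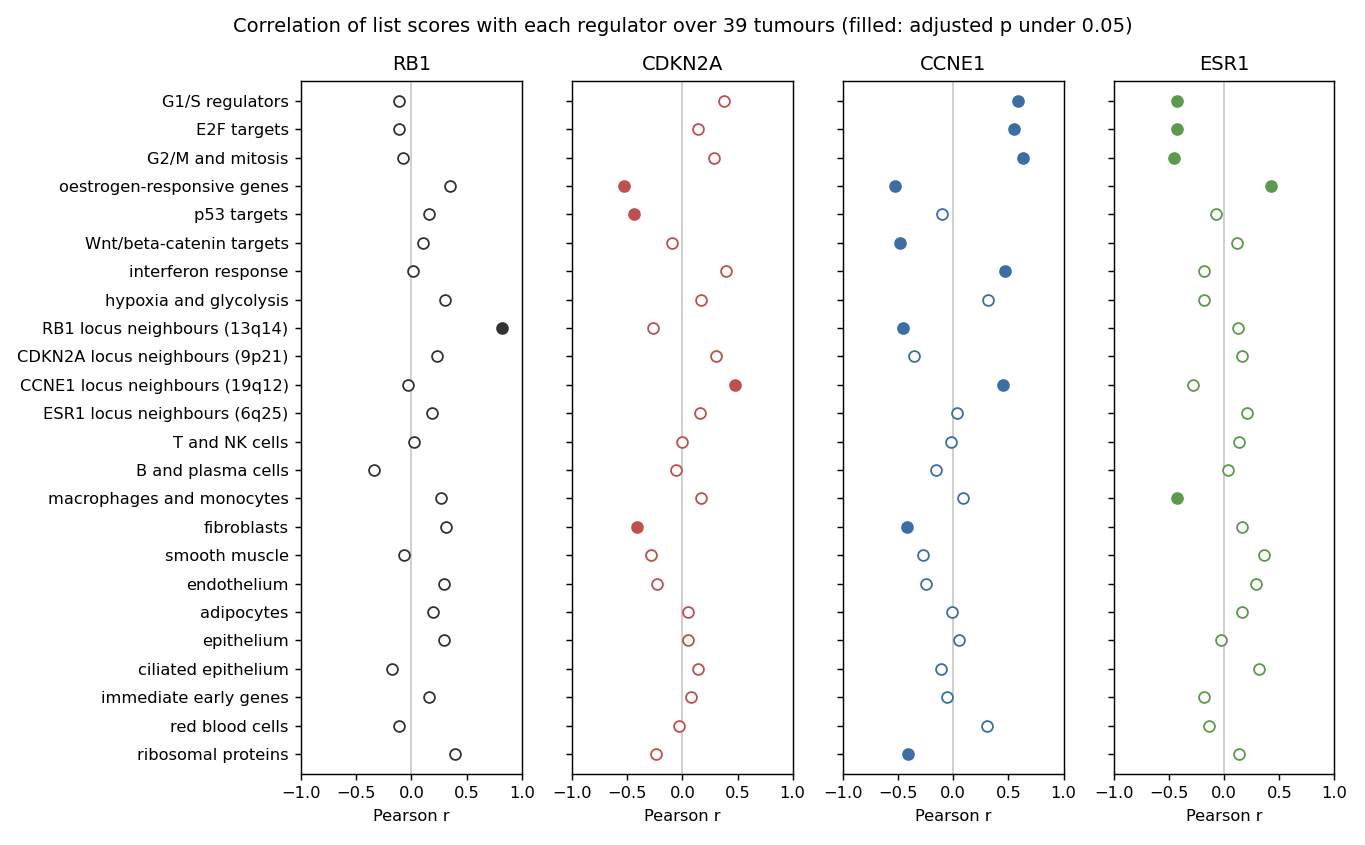
Pearson r over 39 tumours between the score of each of 24 gene lists and the log2 CPM of RB1, CDKN2A, CCNE1 and ESR1, with filled points at an adjusted permutation p under 0.05 over 96 relations. The largest is that of the 13q14 genes with RB1 (r = 0.821), and CCNE1 has 10 filled points, ESR1 5, CDKN2A 4 and RB1 1.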

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

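The GC trend, the macrophage score, the removal of the 5 tumours under 10000000 counts, and DESeq2 and limma for ESR1 without its 2 farthest tumours were chosen after the data were seen, and the other alternatives were planned. The levels of all 30 G1/S regulators moved by less than 1 SD with DESeq2's size factors and with a prior count of 0.5. Of the alternative values for pairs and for counts of genes and lists, 105 kept their side of the threshold or stayed within 1.5 times the count and 35 did not, and with DESeq2's size factors all of them did. Where a value below names fewer tumours or another test, that is what changed, and for the rest the cause was not tested. CDKN2D had fewer than 10 counts in 20 tumours and at most 101 in any, and whether depth limits it was not tested. With these libraries, simulated slopes of 0.25 and 0.5 per SD were recovered in 5.88% and 39.4% of genes for RB1, and depth was not varied.

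For RB1, with 1300 called (455 higher, 845 lower), the count was 2591 with DESeq2, 3968 with no filter on low counts, 2258 with normal scores, 2375 without the 2 farthest tumours, 26 with library size and genes detected, 382 with fibroblast and T cell scores (165 higher, 217 lower), 53 with the GC trend (24 higher, 29 lower) and 103 without the tumours under 10000000 counts (52 higher, 51 lower). Limma called 1273, of which 850 were higher and 423 lower, and 594 of the 1300 stayed called in the same direction. For CDKN2A, with 102 called (55 higher, 47 lower), it was 458 with DESeq2, 49 with limma (44 higher, 5 lower), 61 with normal scores (44 higher, 17 lower), 435 without the 2 farthest tumours (356 higher, 79 lower), 48 with fibroblast and T cell scores (7 higher, 41 lower) and 59 with the GC trend (20 higher, 39 lower). For CCNE1, with 801 called (507 higher, 294 lower), it was 1479 with DESeq2, 1553 with limma (736 higher, 817 lower), 427 with normal scores, 267 with fibroblast and T cell scores and 1537 without the tumours under 10000000 counts. For ESR1, with 227 called (65 higher, 162 lower), it was 690 with DESeq2 (344 higher, 346 lower), 141 with limma (73 higher, 68 lower) and 146 with normal scores. Without its 2 farthest tumours edgeR called 0 (1495 at an unadjusted p under 0.05), DESeq2 68 and limma 50. Of the 227, 16 and 11 stayed called in the same direction with DESeq2 and limma.

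For lists, RB1 had 1 called, with 3 given library size and genes detected and 4 without the 2 farthest tumours. CDKN2A had 4, with 1 given fibroblast and T cell scores, CCNE1 had 10, with 6 given those scores (where the fibroblast list was not tested), and ESR1 had 5, with 2 without its 2 farthest tumours and 0 without the tumours under 10000000 counts (6 at an unadjusted p under 0.05), where r was from -0.431 to -0.396 for the 4 lower lists and 0.44 for the higher one, about as large as over all tumours. Limma's camera with an estimated correlation called 0 lists for CDKN2A, CCNE1 and ESR1, with 5, 7 and 4 at an unadjusted p under 0.05, and with the preset correlation 12, 14 and 12. Given fibroblast and T cell scores, most lists that stayed called for CDKN2A, CCNE1 and ESR1 had adjusted p = 0.0487 (permutation test), just under the threshold. The correlation of ESR1 with the E2F target score was -0.325 without the 2 farthest tumours (adjusted p = 0.1). The median r of genes within 2 Mb of CDKN2A was 0.271 and turned to -0.164 without the 2 farthest tumours, an alternative chosen after the data were seen. Among named genes, CA12 with CDKN2A turned to 0.0092 without the 2 farthest tumours (adjusted p = 0.988), and C1QB with ESR1 to 0.018 with the macrophage score, of which C1QB is a member (adjusted p = 0.962), and to 0.0018 with limma without the 2 farthest tumours (adjusted p = 0.998).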

Other observations

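The relations between lists, those of genes beside CCND1, the test of NRF2 targets, the depth and stroma tests for RB1, the depth tests for chromosome neighbours and their values without the 2 farthest tumours, the slope bound for macrophages, the test of the 2 tumours farthest in ESR1 and the shuffled orderings were chosen after results were seen. Tumours with higher scores of E2F targets had lower scores of stromal markers. Pearson r with the E2F target score was -0.641 for endothelium (permutation p = 2e-05, adjusted p = 0.000613 over 276 list pairs, Spearman rho = -0.662, p = 4e-05, adjusted p = 0.001, r = -0.624 without the 2 farthest tumours), -0.625 for smooth muscle (p = 2e-05, adjusted p = 0.000613, rho = -0.629, p = 4e-05, adjusted p = 0.001, r = -0.596) and -0.58 for fibroblasts (p = 4e-05, adjusted p = 0.001, rho = -0.634, p = 1e-05, adjusted p = 0.000552, r = -0.551). The interferon response score rose with the G2/M score (r = 0.533, p = 0.00042, adjusted p = 0.00464). Spearman's rho was 0.5 (p = 0.00121, adjusted p = 0.0134), with r = 0.587 without the 2 farthest tumours. The oestrogen-responsive score was lower where the interferon score was higher (r = -0.517, p = 0.00085, adjusted p = 0.00869, rho = -0.527, p = 0.00069, adjusted p = 0.00866, r = -0.439) and rose with ribosomal protein genes (r = 0.559, p = 0.00027, adjusted p = 0.00373, rho = 0.62, p = 6e-05, adjusted p = 0.00127, r = 0.603). T and NK cell markers rose with B and plasma cell markers (r = 0.605, p = 8e-05, adjusted p = 0.00158). Spearman correlation was 0.591 (p = 0.00018, adjusted p = 0.00328), with r = 0.644 without the 2 farthest tumours. The hypoxia and glycolysis score rose with epithelial markers (r = 0.577, p = 0.00015, adjusted p = 0.0023). Spearman correlation was 0.554 (p = 0.00032, adjusted p = 0.00465), with r = 0.513 without the 2 farthest tumours. In all, 42 of the 276 pairs passed.

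Distances between genes are between their midpoints. For CCND1 (chromosome 11, 69641156 to 69654474) the median r of the 25 genes within 2 Mb was 0.278, above 98.9% of 10000 runs of as many neighbouring genes on other chromosomes, and it was 0.0172 for genes at 2 to 10 Mb. Without the 2 farthest tumours the median within 2 Mb was 0.0522 (percentile 55.4), so it rests on those 2. ALDH3B2, an aldehyde dehydrogenase gene 1.98 Mb away, gave r = 0.543 (permutation p = 0.00031, adjusted p = 0.00367 over 71 relations, rho = 0.537, p = 0.00042, adjusted p = 0.00746, r = 0.456 without the 2 farthest tumours), and DHCR7, a gene of cholesterol synthesis 1.79 Mb away, r = 0.508 (p = 0.00079, adjusted p = 0.00801, rho = 0.409, p = 0.0105, adjusted p = 0.0601, r = 0.351). CTTN, the cortactin gene, did not pass (r = 0.341, p = 0.0323, adjusted p = 0.0819). Spearman correlation was 0.111 (p = 0.498, adjusted p = 0.654), with r = -0.0217 without the 2 farthest tumours. Within 2 Mb of CDKN2A the median r of 7 genes was 0.271 (percentile 97.4) and turned to -0.164 without the 2 farthest tumours (percentile 16), and MTAP had the highest (r = 0.5, p = 0.00373, adjusted p = 0.0241). Spearman correlation for MTAP was 0.183 (p = 0.261, adjusted p = 0.488), with r = 0.209 without the 2 farthest tumours. Within 2 Mb of ESR1 the median r of 13 genes was 0.0535 (percentile 74.5). Correlations over neighbouring genes are across genes, which are not independent replicates.

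The 4 tumours with the highest CCNE1 differed in cell cycle scores. At CCNE1 of 6.33, 6.37, 6.37 and 6.43 log2 CPM, the G2/M scores were 0.58, -1.19, 1.18 and -1.06, and 3 of the 4, including the 2 with low scores, were among the 5 tumours with fewer than 10000000 counts. These tumours were picked after their values were seen.

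Genes associated with RB1 numbered 1300, and of 26 orderings of the tumours, 25 of them shuffled, 1, the real one, gave as many (highest other 79). Chance pairing is thus argued against as the whole source, though 25 shuffles are too few to exclude it. Stroma and T cell content is argued against as the whole source, since 333 of the 1300 remained called with both scores in the model and the median slope went from 0.50 (SE 0.14) to 0.40 (SE 0.14). GC content bias is a candidate explanation, because across genes, which are not independent replicates, the slope fell with GC share (rho = -0.309), higher genes averaged 44.4% GC and lower ones 56.8%, and with the GC trend in the model 42 remained called, with a median slope of 0.29 (SE 0.14). Library depth and RNA yield cannot be told apart from RB1 itself, since 26 genes remained called with depth in the model, where 1297 kept their sign and the median slope was 0.33 (SE 0.15), and RB1 shares variation with library size. The calls ended through smaller slopes at about the same SE, and apart from cell content no biological explanation was tested, as the labels give no groups.

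Genes near RB1 on chromosome 13 followed RB1 by distance, with a median r of 0.418 for 20 genes within 2 Mb, 0.25 at 2 to 10 Mb, 0.147 at 10 to 30 Mb and 0.0296 on other chromosomes. The first lay at percentile 100 of 10000 runs elsewhere, and was 0.349 without the 2 farthest tumours (percentile 100), so a change shared along the chromosome, such as loss or gain of a segment in some tumours, may account for it, though DNA was not measured. For CCNE1 the 6 genes within 2 Mb had a median r of 0.24 at percentile 94.9, between the bounds set for it. The median was 0.397 (percentile 99.2) given library size and genes detected and 0.316 (percentile 98.3) without the 2 farthest tumours, both above the bound for a shared change. With 6 genes and settings on either side of that bound, such a change cannot be told apart from runs elsewhere. Depth is argued against as the whole source for both, since the partial correlation of the neighbour score given library size and genes detected was 0.781 for RB1 (permutation p = 2e-05) and 0.525 for CCNE1 (p = 0.00023), where the neighbour list also holds genes over 2 Mb away. Other than a shared change along the chromosome, no biological explanation was tested, because the labels give no groups.

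Genes associated with ESR1 numbered 227, with 1 of 26 orderings, the real one, giving as many (highest other 44). This argues against chance pairing as the whole source, though 25 shuffles are too few to exclude it. A few tumours at the ends of the ESR1 range cannot be told apart from a trend over all tumours, since without the 2 farthest 217 of 227 kept their sign while the median slope went from 0.510 (SE 0.118) to 0.368 (SE 0.187), and the wider SE keeps it open. With the macrophage score in the model 105 of the 227 remained called, fewer than the bound set in advance asked for to argue against macrophage content. The median slope was 0.461 (SE 0.134), which argues against macrophage content as the whole source only by a bound added after results were seen. A part in the other calls stays open. Apart from cell content no biological explanation was tested, as the labels give no groups. For CDKN2A and CCNE1, with 102 and 801 called, 1 of 26 orderings, the real one, gave as many in each case (highest other 40 and 7). Chance pairing is argued against there too, with the same limit. At least 1 gene was called in 9, 11, 8 and 14 of the 25 shuffled orderings for RB1, CDKN2A, CCNE1 and ESR1, more often than a threshold of 0.05 allows for independent genes, so some false calls remain likely. Across genes, slopes also varied with GC share for CDKN2A (rho = 0.296), CCNE1 (0.222) and ESR1 (-0.121). Genes higher with CDKN2A averaged 55.8% GC and lower ones 44.8%. With the GC trend in the model, 49 of the 102 CDKN2A genes remained called, at a median slope of 0.61 against 0.68. For CCNE1 570 of 801 remained, and for ESR1 182 of 227. A part of GC content bias thus stays open for these regulators too.

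The decrease of AKR1B10, ME1 and CBR1, among other genes, with ESR1 led to a hypothesis that tumours with lower ESR1 may have more RNA of NRF2 targets, genes of the oxidative stress response. A list of NRF2 targets was tested without the members seen first, a choice made after the value over all members was seen. The tumours were the same ones in which the hypothesis arose, and genes of a list can vary together. Leaving out those members therefore does not make the test independent, and its p-values do not allow for that selection. The values describe these tumours and cannot decide the hypothesis. The score of the 16 other members was lower in tumours with more ESR1 (Pearson r = -0.389, permutation p = 0.0301, adjusted p = 0.0373 over 4 relations). Spearman correlation was -0.489 (p = 0.00173, adjusted p = 0.00346). Without the 2 farthest tumours r was -0.471 (p = 0.00275) and rho -0.477 (p = 0.0032). Over all tumours, 8 of the 16 genes were lower by edgeR's test, which called 0 genes for ESR1 without the 2 farthest tumours. With CDKN2A the same score gave r = -0.361 (p = 0.0281, adjusted p = 0.0373) but rho = -0.0326 (p = 0.844, adjusted p = 0.844) and r = 0.0139 without the 2, so that relation rests on those tumours.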
